A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

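Total RNA of 10 Saccharomyces cerevisiae samples was measured on 10 arrays with 2 channels each. Per the labels, 5 arrays hold strain DBY8778 and 5 hold a KIN82 deletion, at 0, 5, 15, 30 and 60 min of heat shock, with 1 array per strain and time, and the other channel of every array holds a reference whose makeup is not given in the sources used here. DBY8778 was taken as the wild type because the labels describe the samples as wild type and kin82 mutant and no other strain is named. The titles of the deletion arrays at 0 and 60 min carry the word repeat, and the DBY8778 titles name a second heat shock, so the strains may come from separate time courses.

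The deposited values are log ratios of the 2 channels, and were read as log2 ratios. The base of the logarithm is not given in the sources used here. Base 10 would put the highest ratios beyond the range of scanners of that kind, while a natural logarithm cannot be excluded and would make every log2 value printed here larger by one common factor. The scanner, the dyes, the background correction, the normalization and the filters that the authors used are not given in the sources used here. The array medians as deposited lay between -0.15 and 0.03. The table holds 5983 rows named by open reading frame, of which 5170 have a value on all 10 arrays, 693 on 9 and 120 on 8. Of these rows, 338 hold values with at most 2 decimals on every array, for an unknown reason. Gene symbols were taken from the RefSeq gene table of assembly R64 by locus tag for 5484 rows, and the other 499 rows keep their systematic names. No coordinates are given, since no genome build is named for the arrays. KIN82 itself was not analysed here, so the deletion could not be checked on the arrays. Precision is limited by the number of arrays, and spot intensities were not used here.

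The direction of the ratio was set by a rule fixed before the data were examined, as were the comparisons, the gene lists, the rule for named genes and the alternatives unless stated otherwise. Because KIN82 could not decide it, the ratio was to be read as sample over reference if at least 80% of a list of Hsf1-dependent chaperones was higher at 15 min than at 0 min in both strains. This held for 26 of 29 chaperones in the wild type (89.7%) and 27 of 29 in the deletion (93.1%), so sample over reference is the likely direction. The rule sets the sign of the chaperone list by construction, and that list is therefore not independent evidence of its direction during heat.

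Each array was centred on its median. Genes with a value on both 0 min arrays and on at least 8 of the 10 arrays were tested, which left 5744. The values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with time as a factor plus strain, which leaves 4 residual degrees of freedom, to which the prior added 11.0 (prior SD 0.31). Because no strain and time combination has a second array, the residual holds both array noise and any strain by time interaction. From this fit came the change at each time against 0 min, the heat average (the mean of 5, 15, 30 and 60 min minus 0 min), an F test over the time course and the difference of deletion minus wild type over all 5 times. A strain by heat term was added for the strain-dependent response, with 3 residual degrees of freedom. It rests on 1 pair of arrays at 0 min. The labels do not say whether the times of a strain came from 1 culture or from separate cultures. Samples of 1 culture would not be independent of each other. No strain and time has a second sample, so p-values set additive strain and time effects against a residual that holds any departure from additivity. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with calls at an adjusted p under 0.05. Changes are given as log2 values with the standard error of the limma fit. A gene lacking a value on both arrays of a time was left out of the heat average and the F test, which left 5734.

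Of 40 gene lists written in advance, 37 had at least 4 genes with a value on all 10 arrays and were tested with camera at a preset correlation of 0.01 on the 5170 complete genes. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera has no more than the residual degrees of freedom of the fit. For heat and strain it estimated 0.157 for the chaperones, 0.534 for cytosolic ribosomal proteins and 0.59 for tRNA synthetases. Some other lists lay near the preset 0.01. Few degrees of freedom and high correlations can both make its p-values large, and their shares were not tested. The preset p-values treat the genes of a list as nearly independent. Within each list, genes were also counted with p-values adjusted over the list alone. Medians of lists at single times were set against 10000 random lists of the same size, matched in 10 bins on mean log2 ratio over all arrays. That mean itself holds heat and strain effects, and random lists do not keep the correlation among genes of a list. The percentiles are therefore descriptions and do not measure chance.

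The genes named are KIN82's homologue FPK1 and the genes next to KIN82, the 10 largest rises and 10 largest falls of the heat average with the same sign at all 4 times in both strains, the 10 genes most higher and the 10 most lower in the deletion with the same sign at all 5 times, up to 5 genes each way for the strain-dependent response, and up to 4 members with the largest change from each list described. Other genes named, chiefly in the passages on single times, are marked as chosen after their values were seen.

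The fits were tested on simulated data for 5170 genes. For the strain difference, 10.4% of genes planted with a log2 change of 0.5 were recovered, 91.0% at 1 and 100% at 2. For the heat average the shares were 13.4%, 70.1% and 100%. For the strain-dependent response they were 0%, 1.49% and 31.8%. On 37 simulated lists, both planted lists were called and 0 others. The simulated genes varied independently of each other, so this does not test list calls among correlated genes. Alternatives were values as deposited without centring, quantile normalization, scaling to equal median absolute deviation, centring on genes outside the stress and ribosome lists, 2 other filters on missing values, robust eBayes, array weights, leaving out both arrays titled repeat, leaving out each array in turn, subsets of the times, no time term, a trend in place of the heat term, and a further minimum of 2-fold.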

Results

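The series followed gene expression in budding yeast through a heat shock in a wild-type strain, DBY8778, and in a strain lacking KIN82. This gene encodes a protein kinase related to Fpk1 and linked to the regulation of the plasma membrane lipid flippases. Each of the 10 arrays compared 1 sample with a reference RNA, at 0, 5, 15, 30 or 60 min, so that each strain and time is represented by 1 array. Between 5844 and 5949 genes had a value per array, and the share of missing values was at most 2.32%. The questions addressed were how transcript levels changed with heat, how the strains differed and whether the deletion changed the heat response. Values are log2 ratios over the reference, each array centred on its median. The base and the direction of the deposited ratios were not stated, and sample over reference is the likely direction, from the rise of 26 of 29 chaperones in the wild type and 27 of 29 in the deletion at 15 min. KIN82 was not analysed here.

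Heat raised stress gene transcripts and lowered those of ribosome production and translation. Over 5 to 60 min, HSP12, a membrane-protecting small heat shock protein, rose by 3.92 ± 0.54 (SE) on the log2 scale, or 15.1-fold. Its mean change was 5.69 in the wild type and 2.15 in the deletion. For a gene with all values, leaving out the 0 min array of 1 strain gives the mean change of the other strain. AHA1, a co-chaperone of Hsp90, rose by 2.75 ± 0.22, HSP26, a small heat shock chaperone, by 2.70 ± 0.28, and ARO10 and ARO9, enzymes of aromatic amino acid breakdown, by 2.74 ± 0.30 and 2.41 ± 0.31. CAR2, ornithine transaminase of arginine breakdown, rose by 2.45 ± 0.24. The remaining genes among the 10 largest rises with the same sign at all 4 times in both strains were NQM1 (2.51 ± 0.34, and 1.53 and 3.49 without the wild-type and the deletion 0 min array), TFS1 (2.35 ± 0.30), YGP1 (2.22 ± 0.36) and YHR140W (2.18 ± 0.34). In limma with Benjamini-Hochberg adjustment, the adjusted p of these 10 genes lay between 8.36e-06 (AHA1) and 0.000698 (YGP1). Without the wild-type 0 min array YHR140W was at 1.49 ± 0.43 (limma adjusted p = 0.0708, range over alternatives 5.04e-06 to 0.0708).

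The 10 largest falls with the same sign at all 4 times in both strains began with BSC1 (-4.18 ± 0.35) and YDL038C (-3.92 ± 0.33), adjacent open reading frames, and PRM7 next to them was at -3.08 ± 0.30. DBP2, an RNA helicase, was at -3.26 ± 0.31 and YHB1, the flavohaemoglobin that detoxifies nitric oxide, at -3.22 ± 0.30. YGR160W fell by 3.16 ± 0.36 on the log2 scale, but this frame overlaps NSR1 on the opposite strand, and the array values cannot be taken to separate the pair. YEF3, translation elongation factor 3 (-2.77 ± 0.29), URA1 of pyrimidine synthesis (-2.70 ± 0.25), RMT2 (-2.60 ± 0.31) and NOP56, a protein of small nucleolar ribonucleoproteins (-2.59 ± 0.33), completed the 10 falls. Their limma adjusted p lay between 8.36e-06 (BSC1) and 0.00015 (NOP56).

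Of 29 measured Hsf1-dependent chaperones, 16 rose and 2 fell in the heat average, with 18 rising and 2 falling when adjusted over the list alone. HSP78 rose by 2.06 ± 0.26 and SSA3 by 2.05 ± 0.32. Of 31 measured targets of Msn2 and Msn4, the general stress transcription factors, 24 rose and 0 fell (26 adjusted over the list alone), and all 31 had a positive change. Of 21 genes of trehalose and glycogen metabolism, 11 rose (14 adjusted over the list alone), among them GSY2, glycogen synthase (1.87 ± 0.29), PGM2, phosphoglucomutase (1.97 ± 0.46), GDB1, the glycogen debranching enzyme (1.77 ± 0.40), and NTH1, neutral trehalase (1.69 ± 0.28). Camera called these lists with adjusted p of 2.61e-10, 6.01e-17 and 6.96e-08, and each had adjusted p = 0.214 with an estimated correlation.

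Ribosome production moved the other way. Of 57 ribosome biogenesis genes, 48 fell and 0 rose (52 fell adjusted over the list alone), with NSR1, the yeast nucleolin, at -3.55 ± 0.31 on 9 arrays, GAR1 at -2.52 ± 0.32 and NOP7 at -2.47 ± 0.26. Of 134 cytosolic ribosomal protein genes, 119 fell and 0 rose (131 fell adjusted over the list alone), with RPS2 at -2.30 ± 0.29 and RPL9A at -2.10 ± 0.26. Many ribosomal protein genes have near-identical paralogues, which the probes may not have separated. Subunits and initiation factors of RNA polymerases I and III fell in 10 of 23 cases (12 adjusted over the list alone), with RPA49 at -2.29 ± 0.24 and RPA135 at -1.94 ± 0.25. Translation factors fell in 21 of 35 cases (24 adjusted over the list alone) and aminoacyl-tRNA synthetases in 10 of 17 (13 adjusted over the list alone). The camera adjusted p of these 5 lists lay between 4.13e-49 (ribosomal proteins) and 4.57e-07 (polymerases), and with an estimated correlation it lay between adjusted p = 0.214 and adjusted p = 0.324.

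Smaller shifts were seen in metabolism. Of 23 tricarboxylic acid cycle genes 7 rose and 1 fell, with citrate synthase CIT1 at 1.35 ± 0.29 and isocitrate dehydrogenase IDH2 at 1.32 ± 0.25. Of 16 glycolysis genes 4 fell and 0 rose, with pyruvate kinase CDC19 at -1.24 ± 0.29. Of 43 amino acid biosynthesis genes 12 fell and 2 rose, led by the branched-chain transaminase BAT1 (-1.87 ± 0.26). Adjusted over the list alone, 9 rose and 1 fell in the first list, 4 fell in the second, and 18 fell and 3 rose in the last. Camera gave adjusted p of 0.000942, 0.0118 and 0.000214 for these lists, and adjusted p = 0.214, adjusted p = 0.315 and adjusted p = 0.317 with an estimated correlation.

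More genes were called at 15 min than at the other times, under every alternative tried. With 2 arrays at each time against the 2 at 0 min, limma with Benjamini-Hochberg adjustment called 489 genes at 5 min (215 higher, 274 lower), 1354 at 15 min (546 higher, 808 lower), 715 at 30 min (248 higher, 467 lower) and 80 at 60 min (28 higher, 52 lower). Without the wild-type 0 min array these counts were 126, 730, 228 and 23, and without the deletion 60 min array 6 genes were called at 60 min. The low count at 60 min depended on the scaling, with 566 genes at 60 min against 136 at 5 min after quantile normalization, and 514 against 346 after scaling to equal median absolute deviation. The median chaperone changed by 1.85 in the wild type and 1.5 in the deletion at 5 min, and by -0.36 and 0.27 at 60 min. Ribosome biogenesis genes had medians of -2.36 and -2.18 at 15 min and -0.53 and -0.19 at 60 min. Cytosolic ribosomal proteins had medians of -1.02 and -0.16 at 5 min and -2.58 and -1.92 at 15 min, with 10 of 134 called lower at 5 min and 129 at 15 min, and ribosome biogenesis genes had 42 and 53 of 57. A difference in timing between these lists was not tested. At 0 min the median chaperone already lay 1.78 above the reference in the wild type and 0.70 above it in the deletion.

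**Figure D1:**
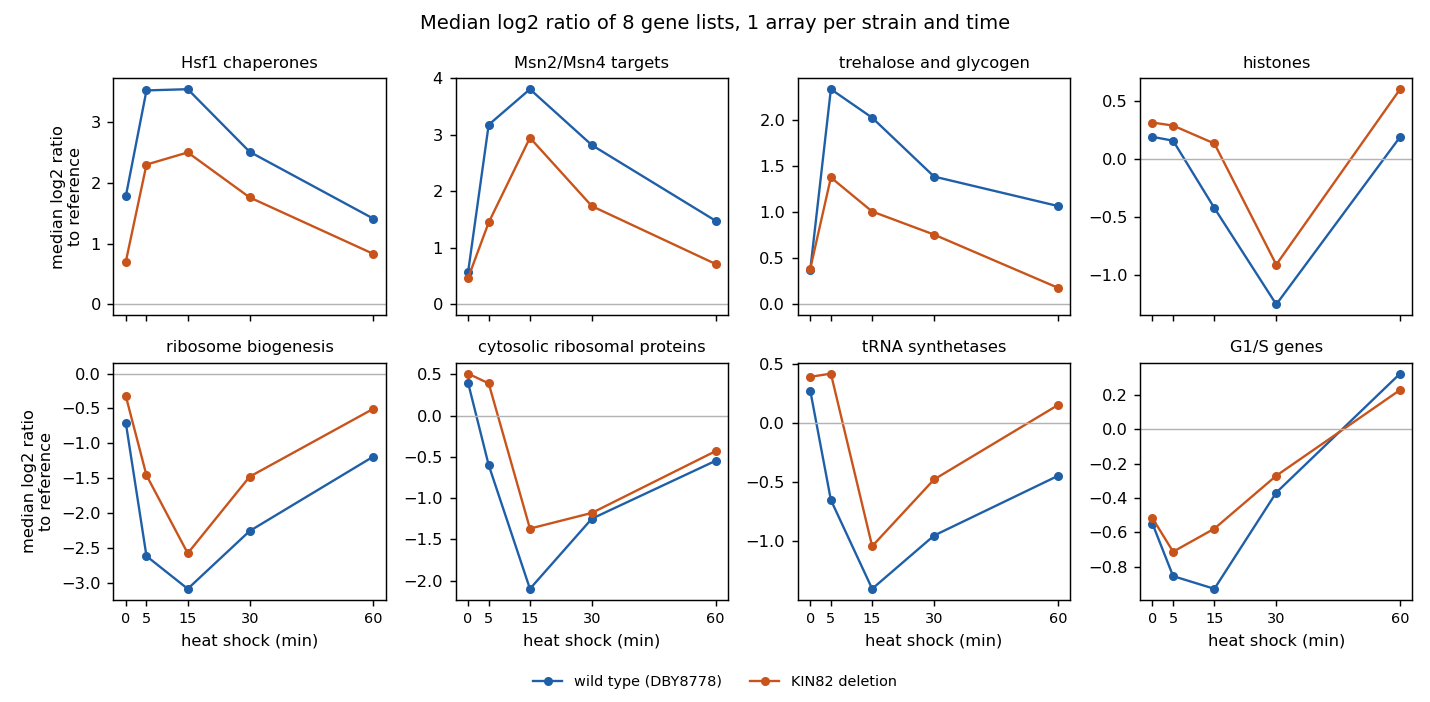
Median centred log2 ratio to the reference (vertical axes, scaled per panel) of 8 gene lists against minutes of heat shock, with wild type in blue and the KIN82 deletion in orange, and each point from 1 array. Stress lists peak at 5 or 15 min, at 3.54 in the wild type and 2.50 in the deletion for the chaperones at 15 min, and ribosome biogenesis has its lowest medians at 15 min, at -3.09 and -2.58.

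In all, 921 of 5734 genes changed in the heat average (330 higher, 591 lower), 630 of them by at least 2-fold, and 1344 changed by the F test over the time course. Camera called 19 of 37 lists, 11 up and 8 down, and fry called 17, while 0 calls held with an estimated correlation. After quantile normalization camera called 14 lists, 6 up and 8 down, of which 12 were among the 19. The heat average rested partly on the 0 min arrays, with 191 genes called without the wild-type 0 min array and 500 without that of the deletion. At 60 min quantile normalization moved the share of higher genes from 35% to 47.3%, and 10 genes were called without both arrays titled repeat.

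Averaged over the 5 times, the deletion strain had lower levels of chaperones and general stress genes and higher levels of ribosome biogenesis genes than the wild type. TMA10, a stress-induced ribosome-associated protein, was lower by -2.32 ± 0.25 (SE, log2), or 5.0-fold, and BTN2, a protein-sorting factor of misfolded proteins, by -2.22 ± 0.24 (-0.92 after quantile normalization). HCA4, an RNA helicase of ribosome assembly, was higher by 2.17 ± 0.24, or 4.49-fold, LCP5 by 1.89 ± 0.23 and KRI1 by 1.88 ± 0.28 (0.93 with only the 0 and 60 min pairs). In limma, TMA10, BTN2 and HCA4 had the lowest adjusted p of all genes, 0.000346. Each differed in the same direction at all 5 times, which the rule for named genes requires.

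Other genes among the 10 most lower in the deletion with the same sign at all 5 times were HBT1 (-1.84 ± 0.27), RTN2 (-1.69 ± 0.29), PGM2 (-1.69 ± 0.36), the co-chaperones STI1 (-1.68 ± 0.23) and SIS1 (-1.67 ± 0.24), the mitochondrial disaggregase HSP78 (-1.62 ± 0.21), the cytosolic disaggregase HSP104 (-1.56 ± 0.28) and AIM17 (-1.54 ± 0.21). Their limma adjusted p lay between 0.0012 (HSP78) and 0.0121 (PGM2). After quantile normalization, HSP78 was at -1.0 ± 0.29 (limma adjusted p = 0.0518, range over all alternatives 3.75e-05 to 0.326), HSP104 at -0.54 ± 0.25 (adjusted p = 0.19, range 0.000824 to 0.364) and AIM17 at -0.42 ± 0.19 (adjusted p = 0.188, range 0.000196 to 0.301). With either 60 min array left out, PGM2 was at -1.67 ± 0.46 (limma adjusted p = 0.0525, range 0.00142 to 0.425), and with either 5 min array left out it was at -1.09. Other genes among the 10 most higher were RSA4 (1.69 ± 0.22), FPR4 (1.61 ± 0.31), the exosome helicase MTR4 (1.55 ± 0.23), PUF6 (1.55 ± 0.21), RPF1 (1.51 ± 0.26), NSA2 (1.49 ± 0.28) and RIX7 (1.48 ± 0.21). Their limma adjusted p lay between 0.00122 and 0.00712. With only the 0 and 60 min pairs, 4 of the genes named here lost the call in limma, FPR4 at 0.67 (adjusted p = 0.232, range over all alternatives 0.0016 to 0.43), RPF1 at 0.91 (adjusted p = 0.0546, range 0.00072 to 0.224), NSA2 at 0.58 (adjusted p = 0.335, range 0.00131 to 0.502) and RTN2 at -0.88 (adjusted p = 0.0692, range 0.000433 to 0.288).

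**Figure D2:**
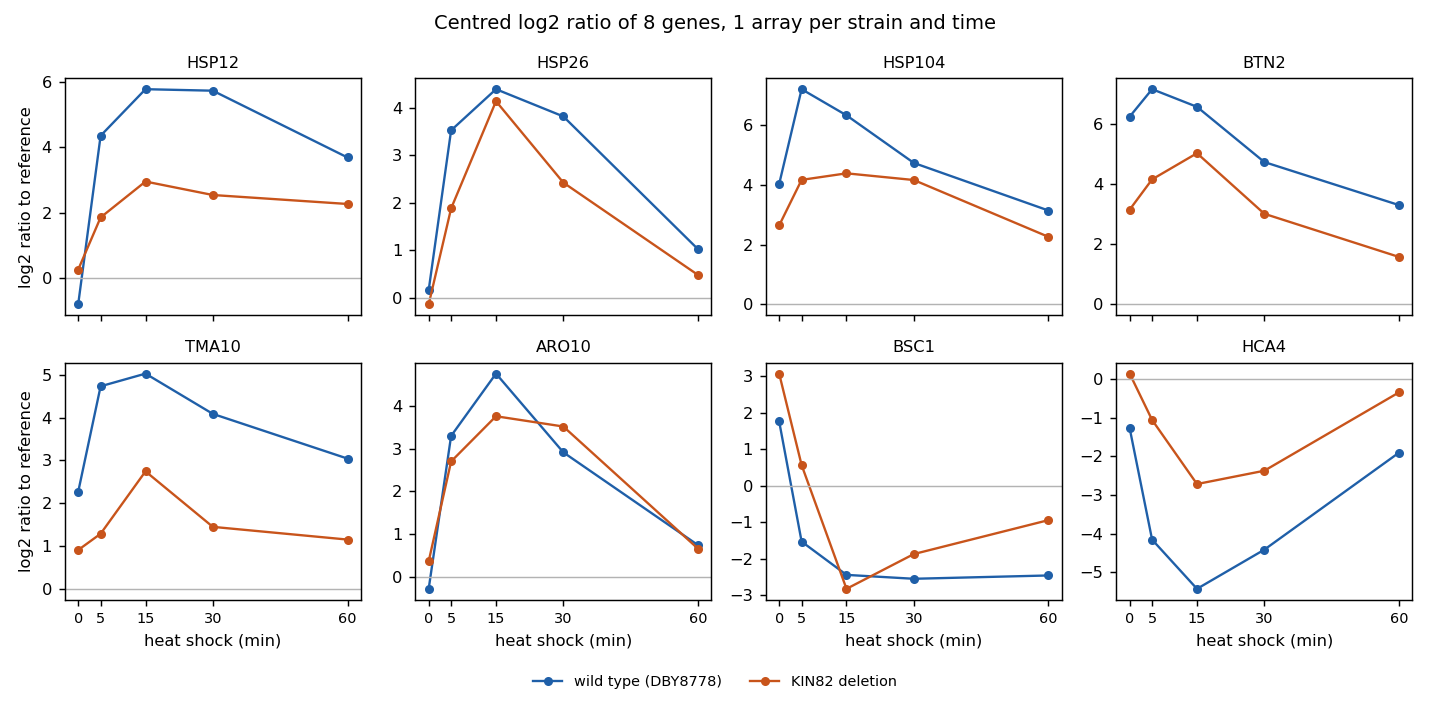
Centred log2 ratio to the reference (vertical axes, scaled per panel) of 8 genes against minutes of heat shock, with wild type in blue and the KIN82 deletion in orange, and each point from 1 array. TMA10 lies between 2.26 and 5.03 in the wild type and between 0.91 and 2.74 in the deletion, and HCA4 lies lower in the wild type at all 5 times.

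Of 29 chaperones, 20 were lower in the deletion and 1 was higher (21 and 1 adjusted over the list alone), with a list median of -0.87 (-0.55 after quantile normalization). Of 31 Msn2 and Msn4 targets, 15 were lower and 1 was higher (23 and 1 adjusted over the list alone). Catalase T, CTT1, was at -1.82 ± 0.26 on 4 pairs of arrays and HSP12 at -1.77 ± 0.43. These are means over times, and HSP12 was not lower in the deletion at 0 min. The median of the Msn2 and Msn4 list was -0.22 at 0 min, with 19 of 31 below 0. It was -1.29, -0.69, -1.01 and -0.98 at 5, 15, 30 and 60 min. Of 21 trehalose and glycogen genes, 10 were lower and 1 was higher (13 and 1 adjusted over the list alone), with GSY1 at -1.48 ± 0.21 and ATH1, acid trehalase, at -1.27 ± 0.22. Camera gave adjusted p of 1.20e-12, 5.47e-12 and 2.78e-06 for these lists, and adjusted p = 0.407 for each with an estimated correlation. Of 57 ribosome biogenesis genes, 26 were higher and 0 lower (41 higher adjusted over the list alone), with a median of 0.64 (0.40 after quantile normalization), NOP2 at 1.41 ± 0.20 and RLP24 at 1.37 ± 0.20. Of 134 ribosomal protein genes, 26 were higher and 0 lower (36 adjusted over the list alone), with RPL4A at 1.12 ± 0.20. The ribosomal protein difference lay mainly at 5 and 15 min. Its list medians were 0.15, 1.06, 0.72, 0.03 and 0.105 at 0, 5, 15, 30 and 60 min. Of 17 tRNA synthetases, 8 were higher (9 adjusted over the list alone), with FRS1 at 1.03 ± 0.23. Camera gave adjusted p of 1.02e-14, 1.63e-10 and 8.67e-06 for these, and adjusted p = 0.407, adjusted p = 0.562 and adjusted p = 0.459 with an estimated correlation.

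In the phosphate regulon, 8 of 15 genes were higher in the deletion and 2 lower (10 and 2 adjusted over the list alone). The list median of deletion minus wild type was 0.81, 1.61, -0.12, 0.52 and 0.67 at 0, 5, 15, 30 and 60 min. VTC4, a polyphosphate polymerase subunit, was higher by 1.63 ± 0.29, the phosphate transporter PHO84 by 1.12 ± 0.26 and VTC3 by 1.01 ± 0.23, while the glycerophosphoinositol transporter GIT1 was at -1.03 ± 0.24. The camera adjusted p was 0.00047, and adjusted p = 0.422 with an estimated correlation. Of 15 sporulation and meiosis genes, 6 were lower and 0 higher (6 adjusted over the list alone), with SPR3 at -1.07 ± 0.26 and ZIP1 at -0.99 ± 0.22 (camera adjusted p = 0.00157, and adjusted p = 0.407 with an estimated correlation). Of 21 iron regulon genes, 3 were lower and 0 higher (3 adjusted over the list alone), and these were the siderophore-binding cell wall mannoproteins FIT3 (-1.50 ± 0.27), FIT2 (-1.40 ± 0.21) and FIT1 (-0.89 ± 0.20). Camera gave the list an adjusted p of 0.0143, and adjusted p = 0.422 with an estimated correlation.

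In total 688 of 5744 genes differed between the strains in limma with Benjamini-Hochberg adjustment, 379 higher and 309 lower in the deletion, and 166 of these by at least 2-fold. Without centring, 673 genes were called and the share that was higher was 65.5% rather than 55.1%. Camera called 16 of 37 lists, 8 each way, of which 0 held with an estimated correlation, and fry called 0. The strain difference cannot be told apart from a difference between time courses, and the count was 284 in the 5, 15 and 30 min pairs alone, 158 in the 0 and 60 min pairs alone and 1 with no time term in the model. It was 429, 421, 249 and 366 with either array at 0, 5, 30 and 60 min left out.

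The strain difference and the heat change ran in opposite directions across genes. Among 5734 genes, 170 were lower with heat and higher in the deletion, against 39.0 in independent lists of the same sizes, and 76 were higher with heat and lower in the deletion, against 17.7. Only 1 gene was higher in both, against 21.8, and 5 were lower in both, against 31.6. Pearson's r across genes between the heat average and the strain difference was -0.44 with a covariance of -0.119, while 20 simulations of unchanged genes with independent noise in the same design gave r between -0.023 and 0.015 and a covariance between -0.00123 and 0.000786. The simulations held no heat change, and in this design such noise gives r near 0 by construction. They therefore do not tell what sharing the arrays would give if arrays differed in spread or errors were shared between genes. They do not bear on a narrower range of ratios on the deletion arrays. Genes are not independent replicates, and both comparisons use the same 10 arrays.

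**Figure D3:**
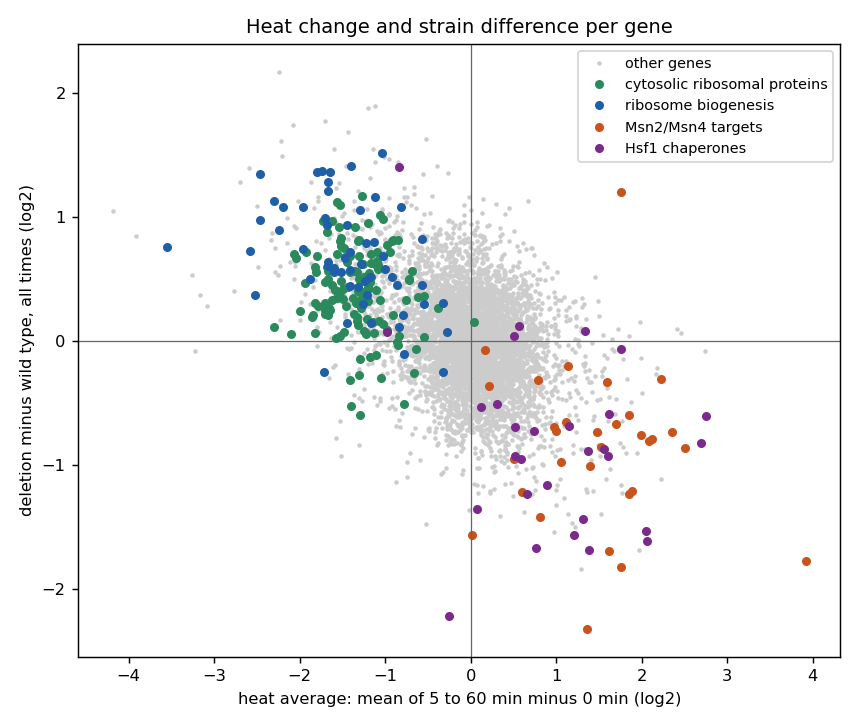
Heat average (horizontal axis, log2) against the difference of deletion minus wild type over all times (vertical axis, log2), with 1 point per gene and 4 gene lists in colour. Ribosome biogenesis genes and ribosomal proteins lie mostly at the upper left, with median strain differences of 0.64 and 0.41, and chaperones and Msn2 or Msn4 targets mostly at the lower right, with medians of -0.87 and -0.79.

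Whether the deletion changed the response to heat was tested with the strain by heat term. The deletion array at 0 min is titled repeat and those at 5, 15 and 30 min are not, so these changes in the deletion may cross separate runs, and the term cannot be fitted without that array. HSP12 changed by 5.69 in the wild type and by 2.15 in the deletion, a difference of -3.54 ± 0.60 that did not pass (limma adjusted p = 0.127). SOL4, a homologue of 6-phosphogluconolactonase, had a mean change of 1.68 in the wild type and -1.66 in the deletion, a difference of -3.34 ± 0.73 (limma adjusted p = 0.924). The polyamine transporter TPO1 was at 1.56 and -0.44, a difference of -2.01 ± 0.50 (limma adjusted p = 0.982). CPP3 and SHC1 had differences of -2.23 ± 0.65 and -2.06 ± 0.60, and SIR4, YJL169W, YGR153W, RAD28 and KRE33 had differences between 1.59 and 1.73, with limma adjusted p = 0.999 for each of these 7 genes. In limma, 0 of 5744 genes passed, and 130 had an unadjusted p under 0.05 where chance gives 287.2. A strain by time trend also gave 0 genes. The residual of the strain by heat fit also holds strain differences between the heated times. On simulated data its test recovered 0%, 1.49% and 31.8% of planted log2 changes of 0.5, 1 and 2. The 0 calls therefore do not show an unchanged response. HSP12 passed after scaling to equal median absolute deviation (-3.62 ± 0.53, limma adjusted p = 0.0154) and with either 60 min array left out (-3.90 ± 0.55, adjusted p = 0.0129), and its adjusted p ranged from 0.0129 to 0.538 over all alternatives.

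Among the gene lists, Msn2 and Msn4 targets had a median difference of response of -0.72, with 27 of 31 below 0 (3 lower adjusted over the list alone, camera adjusted p = 8.57e-12). Trehalose and glycogen genes had a median of -0.43 (camera adjusted p = 0.000936), with 18 of 21 below 0, and plasma membrane drug and polyamine pumps one of -0.52 (camera adjusted p = 0.00287), with 10 of 15 below 0. All 3 lists had adjusted p = 0.407 with an estimated correlation. After quantile normalization these medians were -0.25, -0.11 and -0.54, and after scaling to equal median absolute deviation -0.56, -0.12 and -0.56. Chaperones, not called (camera adjusted p = 0.196), had a median of 0.07, but of 0.94 and 0.57 under these scalings. Ribosomal proteins had a median of 0.38 (camera adjusted p = 2.88e-10, and adjusted p = 0.785 with an estimated correlation), with 110 of 134 above 0. Ribosome biogenesis genes had a median of 0.39 (camera adjusted p = 2.69e-06, and adjusted p = 0.772 with an estimated correlation), with 44 of 57 above 0, but of -0.17 after quantile normalization. The tRNA synthetases had a median of 0.26 (camera adjusted p = 0.0171, and adjusted p = 0.788 with an estimated correlation), with 15 of 17 above 0. Fry called 0 lists, and after quantile normalization camera called 3 lists, of which 1 was among these 6.

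Without a test, the lists can be compared time by time. At 5 min the median Msn2 or Msn4 target had risen by 2.49 in the wild type and 1.07 in the deletion. The difference of changes, -1.30, lay below all 10000 random lists matched on mean log2 ratio over all arrays (percentile 0). At 15, 30 and 60 min the difference for these targets lay at percentiles 0.6, 0.44 and 0.06. The matching mean itself holds heat and strain effects, and random lists do not keep the correlation within a list. Percentiles given here therefore do not measure chance. Trehalose and glycogen genes lay at percentiles 11.1, 7.39, 69.3 and 1.09 at 5, 15, 30 and 60 min. Ribosome biogenesis genes lay at 98.4, 64.8, 96.3 and 92. For chaperones the difference of changes was -0.31 at 5 min (percentile 67.6), 0.05 at 15 min (93.8), 0.24 at 30 min (99.8) and 0.37 at 60 min (100). For ribosomal proteins it was 0.92 at 5 min (percentile 100), 0.66 at 15 min (100), -0.06 at 30 min (1.22) and 0.04 at 60 min (22.7). Across genes, Pearson's r between the changes of the strains was 0.58 at 5 min, 0.78 at 15 min, 0.70 at 30 min and 0.52 at 60 min, and Spearman's rho was 0.49, 0.67, 0.59 and 0.47. These correlations are across genes, which are not independent replicates, and each strain has its own 0 min array.

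The genes next to KIN82 were examined for effects of the deletion at its locus. MSH3, the mismatch repair gene beside KIN82, was lower in the deletion by -0.73 ± 0.18 (limma adjusted p = 0.018) and YCR085W by -0.79 ± 0.23 (limma adjusted p = 0.0422). FIG2 (-0.61 ± 0.20), CDC39 (-0.46 ± 0.20), YCR090C (-0.06 ± 0.18), CDC50 (0.29 ± 0.25), OCA4 (0.35 ± 0.17) and CSM1 (0.23 ± 0.25) did not pass (limma adjusted p between 0.0642 and 0.852). FPK1, the homologue of KIN82, was at 0.05 ± 0.19 (limma adjusted p = 0.885). Both calls were lost under several alternatives, in limma with adjusted p between 0.0165 and 0.28 for MSH3 and between 0.0196 and 0.496 for YCR085W over all of them. Among these were leaving out either 30 min array (0.0654 and 0.199) and leaving out both arrays titled repeat (0.092 and 0.107). MSH3 also lost the call with either 60 min array left out (0.0565), and YCR085W without centring (0.0541) or with either 0 or 5 min array left out (0.132 and 0.0519). In a list of 21 genes of flippases, the Fpk and Ypk kinases and genes around them, 3 were lower in the deletion and 0 higher (3 adjusted over the list alone), the kinase YPK2 (-1.03 ± 0.27), RIM15, a nutrient-signalling kinase of another kind (-0.65 ± 0.19), and CRF1, a corepressor of ribosomal protein genes (-0.62 ± 0.18). The list holds CRF1 through a shared name, and the flippase subunit also called CRF1, YNR048W, named after its value was seen, was at -0.01 ± 0.19. The list was not called by camera (adjusted p = 0.366, and adjusted p = 0.562 with an estimated correlation).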

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

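All tests below were planned before their results were seen except 4, which were chosen after: the chaperone list and the Msn2 and Msn4 targets in the 0 min pair, the medians along chromosomes, and one factor per array. The arrays are 1 per strain and time, so the p-values here set effects against a residual that holds technical spread between arrays and what the fitted terms leave out.

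Camera at the preset correlation called 6 gene lists on the strain by heat term, of which 0 held with an estimated correlation. Msn2 and Msn4 targets had a median difference of -0.72 (27 of 31 genes below 0, camera adjusted p = 8.57e-12), trehalose and glycogen genes -0.43 (adjusted p = 0.000936) and drug and polyamine pumps -0.52 (adjusted p = 0.00287), each with adjusted p = 0.407 with an estimated correlation. After quantile normalization these medians were -0.25, -0.11 and -0.54. Ribosome biogenesis genes had a median difference of 0.39 (camera adjusted p = 2.69e-06, and adjusted p = 0.772 with an estimated correlation), which turned to -0.17 after quantile normalization. Cytosolic ribosomal proteins were at 0.38 (camera adjusted p = 2.88e-10, and adjusted p = 0.785 with an estimated correlation) and tRNA synthetases at 0.26 (camera adjusted p = 0.0171, and adjusted p = 0.788 with an estimated correlation).

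The changes of 3 named genes went one way at all 4 times in one strain and the other way at all 4 times in the other, and this difference was not tested beyond the strain by heat term, which they did not pass. YJL169W had a mean change of -1.20 in the wild type and 0.49 in the deletion, a difference of 1.70, and RAD28 one of -0.87 and 0.73, a difference of 1.60. For CDC39, near KIN82, the difference was -0.62.

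For lower stress genes and higher ribosome biogenesis genes in the deletion, 1 of 100 splits of the arrays drawn from 126 called as many genes, the real one with 688 against 183 for the highest other, but most of these splits are not balanced over times, and swaps of the strain labels within times are too few, 16, to give a share under 0.05, with 688 genes for the real labels and 1 for the highest other. Genes called from the 5 to 60 min pairs alone, 429, had a median difference of 0.54 ± 0.03 (SE over genes) in the same direction at 0 min. The chaperones were at -0.90 ± 0.16 at 0 min. If both 0 min samples were unheated, this argues against a weaker or later heat shock as the whole cause for these genes. That condition was not tested, and the median wild-type chaperone changed by -0.36 from 0 to 60 min. The argument also rests on 1 pair of arrays, the deletion one titled repeat, and an SE over genes does not cover error between arrays. The repeat arrays are not the whole cause, since the chaperone median was -0.72 ± 0.08 in the 0 and 60 min pairs and -0.92 ± 0.15 in the others. Ribosome biogenesis was at 0.56 ± 0.09 and 0.76 ± 0.08 in these pairs. One factor per array that narrows all ratios on the deletion arrays, noise included, is argued against, since their median absolute deviation was lower in 1 of 5 pairs. Scaling to equal deviation could therefore change little and is no further support. After it the chaperone median was -0.83 ± 0.12, with Msn2 and Msn4 targets at -0.80 ± 0.09 and ribosome biogenesis at 0.63 ± 0.08. Noise adds to that deviation, so a narrower signal under wider noise stays open. A narrowing that is not one factor, such as of the extreme ratios alone, stays open, since the SD was lower on the deletion array in 4 of 5 pairs and the chaperone median moved from -0.87 to -0.55 ± 0.14 after quantile normalization, within its error of the bound of -0.44 set for it. A weaker heat shock for Msn2 and Msn4 targets, at -0.22 ± 0.14 at 0 min, stays open too, and the loss of KIN82 cannot be told apart from a difference between time courses, as 0 combinations have more than 1 array.

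At 5 min, Msn2 and Msn4 targets had changed less in the deletion than chaperones had. One common factor for the size of all changes at 5 min was tested by the ratio of the median change in the deletion to that in the wild type. It was 0.81 for chaperones (bootstrap interval 0.677 to 1.09), 0.43 for Msn2 and Msn4 targets (0.301 to 0.512), 0.62 for ribosome biogenesis genes (0.469 to 0.789) and 0.16 for ribosomal proteins (0.035 to 0.221). The highest ratio was 5.13 times the lowest, but this compares the extremes of the lists, chaperones and ribosomal proteins. For chaperones and Msn2 and Msn4 targets the intervals did not overlap. On these intervals alone, this argues against a single factor for these lists. With 1 array per strain and time, the intervals cannot cover error between arrays. A different course of the early response in the deletion may be a candidate explanation, and rests on 1 array per strain at 5 min and at 0 min.

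A whole-chromosome copy number change in the deletion strain would shift a chromosome's median by 0.58 or more. The chromosome median largest in size was -0.12, on chromosome I with 79 genes, under the bound of 0.3, which argues against such a change.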

How the results depend on the processing

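Leaving out 1 pair of times was chosen after seeing the data, and the other alternatives were planned before. No result changed direction among the counts and named genes that were called. Of 790 values of named genes under alternatives, 739 kept their side of the threshold and their direction, 42 lost the call, 2 gained one and 7, none of them called, moved. With single arrays left out, these numbers were 551 of 570, 13, 2 and 4. These values are not separate checks. The looser filter on missing values could not change any of them. Leaving out the arrays titled repeat, or both of their times, gives the same strain fit. So does leaving out either array of a time, or its pair. Among single arrays, such fits were counted for each array, and the 2 gains were HSP12 in the same fit.

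After quantile normalization the counts were 136 genes at 5 min (489 before), 753 at 15 min (1354), 566 at 60 min (80), 762 over the time course (1344) and 395 between strains (688, of which 383 remained). Scaling to equal median absolute deviation gave 514 genes at 60 min, and array weights 278. Scaling also gave 1 gene, HSP12, with a strain-dependent response. Without the arrays titled repeat the counts were 463 for the heat average (921), 236 at 5 min, 861 at 15 min, 411 at 30 min (715), 10 at 60 min, 749 over the time course and 284 between strains, with fewer arrays. The cause was not tested for the scalings and weights.

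Between strains, the count was 1 with no time term, when the spread between times enters the residual, 284 with only 5, 15 and 30 min, 158 with only 0 and 60 min, and 429, 421, 249 and 366 without the 0, 5, 30 and 60 min pair. With a 2-fold minimum it was 166. With no time term 22 named genes lost the call (adjusted p 0.175 to 0.502), and with only 0 and 60 min FPR4, RPF1, NSA2, RTN2, MSH3 and YCR085W did. Camera with an estimated correlation called 0 lists for heat (19), 0 for strain (16) and 0 for the strain-dependent response (6), and after quantile normalization it called 3 for the last, 1 of them the same.

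With each array left out in turn, counts ranged from 191 to 1147 for the heat average, 126 to 650 at 5 min, 730 to 1549 at 15 min, 228 to 897 at 30 min, 6 to 208 at 60 min, 249 to 539 between strains and 0 to 1 for the strain-dependent response. The lowest heat counts came without the wild-type 0 min array, which gave 191, 126, 730 and 228, and without the 0 min array of the deletion they were 500, 274 and 443 for the average, 5 and 30 min. At 5 min the count was 274 without the wild-type 5 min array, at 15 min 895 without that of the deletion, and at 30 min 418 and 278 without the wild-type and the deletion array. At 60 min it was 23 and 13 without the 0 min arrays, 208 without either 5 min array, 53 without either 30 min array, and 13 and 6 without the 60 min arrays. Between strains it was 429, 421, 249 and 366 without either array at 0, 5, 30 and 60 min. HSP12 was the 1 gene called with either 60 min array left out.

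The KIN82 strain difference was not run. The strain-dependent response cannot be fitted without a 0 min array or without both repeat arrays. The looser filter on missing values left the tested genes the same and so tests nothing. No paired analysis was possible beyond time as a factor, because each strain and time has 1 array. Signal over background, which limits weak spots, was not used here.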

Other observations

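The genes and times here were chosen after their values were seen, and no explanation was tested. All 9 histone genes were lower at 30 min than at 0 min, and 8 passed in limma, with a median of -1.52 in the wild type and -1.44 in the deletion. HTA1 was at -1.96 ± 0.33 (limma adjusted p = 0.00131) and HTA2 at -1.81 ± 0.28 (limma adjusted p = 0.000885). At 60 min the list median was 0.21. The G1 and S phase genes were positive at 60 min in 20 of 20 cases, with medians of 0.73 and 0.61, and 3 passed, PCL2 (1.40 ± 0.29, limma adjusted p = 0.0296), MCD1 (1.25 ± 0.29, adjusted p = 0.0452) and CLN2 (1.33 ± 0.31, adjusted p = 0.0462).

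The acid phosphatase PHO5 fell by 2.46 ± 0.31 on the log2 scale at 30 min (limma adjusted p = 0.000279) and was at -0.13 ± 0.31 at 60 min. PHO11 and PHO12, whose near-identical sequences the probes cannot be taken to separate, were at -2.73 ± 0.42 and -2.82 ± 0.39 at 30 min. HSP30, a plasma membrane heat shock protein, was at -2.48 ± 0.32 at 30 min and -2.07 ± 0.32 at 60 min (limma adjusted p = 0.00497). At 0 min BTN2 lay 6.24 above the reference in the wild type and 3.15 in the deletion, and HSP104 4.03 and 2.64.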
